A study of Mus musculus with 4 samples.

How the data were processed

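DNase-seq of CD8-positive naive resting alpha-beta T cells from female B6CASTF1/J mice aged 2 months was deposited as 4 libraries, labelled biological replicates 1 to 4 of a single experiment. The files used for each library were a longer and a shorter peak list, a list of footprints and a list of intervals with a cut rate, all on mouse build mm10 (GRCm38) per the labels. Each list was derived from the library's own filtered alignment, per the text deposited with the library. The aligner, the peak caller and their thresholds are not given in the sources used here.

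The deposited peak value is a signal: the height of each peak, scaled to the depth of its library. All low heights of a library were within 0.05 of a whole multiple of 1 step, for 100% of the values tested, and the reciprocal of the step was read as the number of tags in M (109, 62.9, 91.5 and 24.3 in replicates 1 to 4). The deposited footprint value is a p-value or q-value, which reads as a false discovery rate threshold. It was 0.01 in the first entry of replicate 1, and no check over all entries is reported here. The deposited cut-rate value is a p-value or q-value, read as a false discovery rate per interval, that stays just under 0.05 at its highest. No read counts per site were used, so no counting interval is given for a single site.

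Peaks of the longer lists were merged where they overlapped by at least 1 bp, and sites called in at least 3 of 4 libraries formed the consensus. A site or promoter without a peak in a library was given a height of 0 there. Relative height was the height over the library's median height at the sites called in all 4 libraries. Gene models were those of GENCODE mouse release 21, with 21915 protein-coding genes; a promoter was the sequence within 1 kb of any annotated start of a gene, and a locus the gene body plus 25 kb on each side. Location was compared with 100 random placements of the sites within their chromosomes.

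The 18 gene lists were fixed before the data were examined: T cell identity, CD8 lineage, naive and quiescent T cell, cytotoxic effector and memory, activation and exhaustion, helper and regulatory T cell, thymocyte, NK cell, B cell, myeloid, dendritic and antigen presenting, erythroid and platelet, stromal endothelial epithelial, neural, hepatocyte, housekeeping, cell cycle, and interferon response. All listed genes were found in the annotation, and 1 gene stands in 2 lists. Promoter accessibility of a list was tested with Fisher's exact test (two-sided) against all other protein-coding genes, and locus density against 10000 random lists matched on window length, each with Benjamini-Hochberg adjustment over the 18 lists and a threshold of 0.05. Motif families were 28 consensus sequences written before the data were examined, searched on both strands. Footprints were extended by 5 bp on each side and compared with windows of the same width 100 bp away, with a pseudocount of 0.5 matches. The central 100 bp of sites were compared with windows 1 kb away by Fisher's exact test with adjustment over the 28 families. Values per library were tested with an exact sign-flip permutation over the 4 libraries, for which the smallest two-sided p is 0.13. Copies of a site were exact matches of its central 36 bases on either strand.

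Named genes followed a rule fixed before the data were examined. It took from each list up to 4 members with the highest mean relative height among those called in all 4 libraries and up to 2 members, in alphabetical order, called in none. It added the 10 genes with the most consensus sites at their locus, the 10 highest consensus sites, and a fixed set, of which these are named here: Cd8a, Cd8b1, Cd4, Zbtb7b, Runx3, Tcf7, Lef1, Bcl11b, Ccr7, Il7r, Gzmb, Ifng, Prf1, Tbx21, Eomes, Pax5, Spi1 and Xist. Of motif families it took the 6 highest, the 3 lowest, and AP-1, TCF7/LEF1, RUNX, ETS, CTCF, PU.1, EBF1 and GATA. Trbc2, Cd79a, the Y genes and the genes named in the closing section beyond this rule were chosen after their values were seen.

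Alternatives planned before the data were examined were the shorter peak lists, a consensus of all 4 or of 2 libraries, 50% reciprocal overlap, leaving out each replicate (with all 3 of the others then needed), promoter windows of 0.5 and 2.5 kb, the 5' end of the gene only, locus windows of 5 and 100 kb, no matching on window length, random lists matched on promoter CpG, footprint extensions of 0 and 10 bp, footprint controls 50 and 200 bp away or shuffled, footprints inside consensus sites, site windows of 50 and 200 bp, and cut-rate values below 0.01 and 0.001. Added after seeing the data were replicates 1 and 2 only and an equal number of highest peaks per library. No library was left out of the values reported first.

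The computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Pairwise overlaps were checked against bedtools 2.31.1, and 0 of 12 ordered pairs differed. The steps were tested on simulated data. For consensus sites, 15404 of 20000 simulated sites were planted as consensus and 15404 were found. For gene list promoters over 21915 genes, 79% of planted lists and 0.353% of unchanged lists were called. For locus density the shares were 100% and 0%. The planted list was the naive and quiescent T cell list of 25 genes, so the power of shorter lists was not tested. For consensus site motifs over 5000 sites, a family planted in 10.38% of sites was recovered at 10.34% above controls, and 0 other families were called. The simulated sequence was random with even base shares, so it could not show an effect of base composition. For footprint motifs over 5000 windows, the planted family had a log2 ratio of 8.66 and no other family with 50 matches or more exceeded 0.07. For the deviation of a library at a list's sites, over 17000 sites, the planted library reached the 100th percentile. For the crowding of sites, over 20000 sites, the difference found was 0.83 points with no effect and -19.2 with 20 points planted.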

Results

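DNase-seq, in which DNase I cuts accessible chromatin and the cut ends are sequenced, was measured in CD8-positive naive resting alpha-beta T cells. The cells came from female B6CASTF1/J mice, a cross of a laboratory and a wild-derived inbred strain, at 2 months of age. The 4 libraries carry the labels biological replicates 1 to 4 of a single group, so all comparisons were made between genes, sites or libraries of that group. The longer peak lists held 69413, 70552, 51121 and 20647 peaks in replicates 1, 2, 3 and 4 (mean 52933 ± 23293, SD, n = 4). The smallest step between peak heights implied 109, 62.9, 91.5 and 24.3 M tags in the same libraries. Replicate 4 was the shallowest library, with 4.22 Mb under peaks against 14.7, 13.0 and 11.7 Mb in replicates 1, 2 and 3. The labels name separate biosamples with 1 shared donor identifier and do not say that each came from a separate animal, so p-values over libraries measure only the spread between these libraries. The other p-values compare genes, sites or random placements and measure no spread between animals.

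A first comparison asked whether genes of the CD8 lineage were accessible in every library, as a check of the labels. Cd8a, which encodes the alpha chain of the CD8 coreceptor (GRCm38 chromosome 6, 71373427 to 71379173), had a promoter peak in replicates 1 and 2 with relative heights of 0.498 and 0.366, and none in replicates 3 and 4. A relative height is a peak's height over the median height, in the same library, of the sites called in all 4 libraries. Of the 8 sites within 25 kb of Cd8a called in both replicates 1 and 2, 1 was called in the library labelled replicate 3 and 0 in the library labelled replicate 4. Cd8b1, the beta chain of the same coreceptor, had a promoter peak in all 4 libraries, with relative heights of 1.12, 1.43, 1.03 and 0.596 in replicates 1 to 4 (mean 1.04 ± 0.345, SD, n = 4). Runx3, a transcription factor of the CD8 lineage, was called in all 4 at 1.71 ± 0.312, Patz1 at 1.00 ± 0.235 and Runx1 at 0.757 ± 0.0780. Zbtb7b, the transcription factor of helper T cells, had relative heights of 0.251, 0.358, 0.746 and 1.12 in replicates 1, 2, 3 and 4. In replicates 3 and 4 these were 245% and 369% of the mean of replicates 1 and 2. The 85 other promoters called in all 4 libraries, with heights within 1.5 times that mean and similar CpG content, had medians of 133% and 181%. This comparison was chosen after seeing the data. It took in weak promoters only where replicate 4, the shallowest library, called them, which may itself raise the medians. Cd4, the helper cell coreceptor, had no promoter peak in any library. Of 18 B cell promoters, 10, 10, 13 and 8 were called in replicates 1 to 4, and the 13 in replicate 3 were all those called in any library. Among the 4 highest, Pax5 and Cr2 were higher in replicates 3 and 4 than in replicates 1 and 2. Pou2af1 was lower in both, and Cd22 lay between its values in replicates 1 and 2. Cd79a, a chain of the B cell receptor complex, was called at 0.347 and 0.684 in the libraries labelled replicates 3 and 4 and in neither of the others, and Pax5, a B lineage transcription factor, had relative heights of 0.584, 0.648, 1.02 and 1.67 in replicates 1 to 4. Pou2af1, a lymphocyte transcriptional coactivator, had 1.17, 1.19, 1.07 and 0.842. The library labelled replicate 3 thus went against its label at Cd8a. The library labelled replicate 4 had no call there either. It called only 30.5% of all sites with replicate 1 heights in the range of the 8 Cd8a sites, so its depth stays open as a cause. Zbtb7b was higher in both replicates 3 and 4, at percentiles of 98.8 and 97.6 among the 85 matched promoters. Runx3 was called in both, but at 1.49 and 1.40 it was lower than in replicates 1 and 2 (1.95 and 2.02). Patz1 was higher in both, at 1.23 and 1.12 against 0.947 and 0.695. The lack of a call at Cd4 was shared by all 4 libraries and does not separate them. The Cd8b1 promoter was called in both but was lower in replicate 4, at 46.8% of the mean of replicates 1 and 2. The numbers of gene lists that passed a test are also given below for replicates 1 and 2 only.

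**Figure D1:**
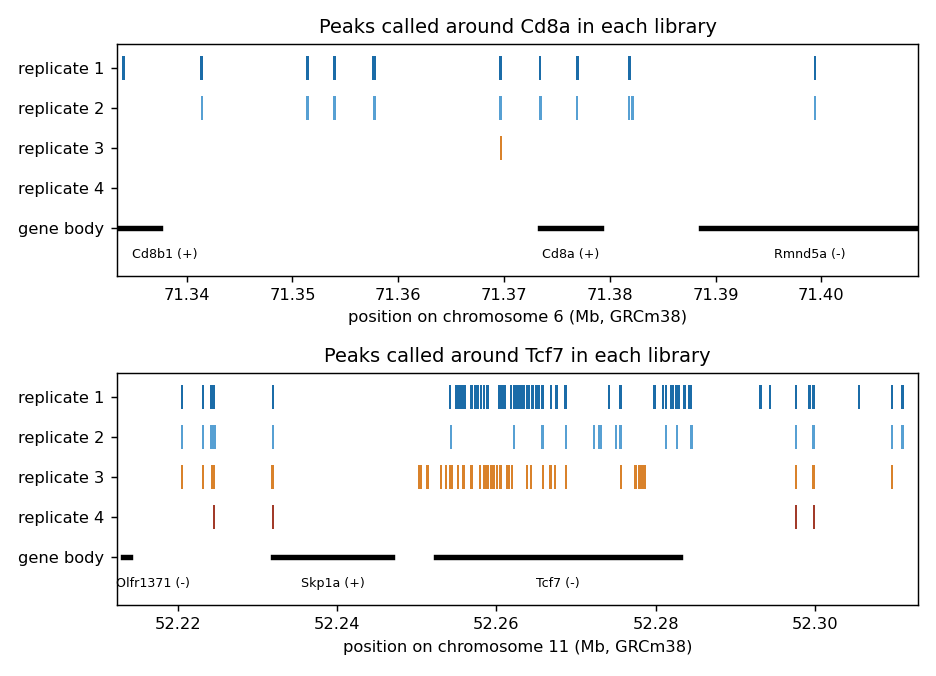
Peaks called around Cd8a and Tcf7 in each library, with position on the chromosome in Mb (GRCm38) on the horizontal axis, 1 line of bars per library, and protein-coding gene bodies as black lines; the narrowest peaks are drawn wider than they are so that they can be seen. Around Cd8a, replicates 1 and 2 show many peaks, replicate 3 shows 1 and replicate 4 shows 0.

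Accessible sites were next compared between the libraries. Merging the 4 peak lists gave 86936 sites, of which 17545 were called in all 4 libraries and 30631 in 1 library. The consensus, sites called in at least 3 libraries, held 41228 sites with a median width of 248 bp and a total length of 12.9 Mb. Over the 12 ordered pairs of libraries, the share of peaks that overlapped a peak of the other library had a median of 78.6% and ranged from 27.0% to 91.5%, against a median of 1.02% after random placement. The lowest shares were those of the other libraries' peaks found in replicate 4, from 27.0% to 36.1%. Across the sites shared by a pair, Spearman's rho of the peak heights lay between 0.835 and 0.948; sites are not independent replicates. The consensus held 17545 sites when all 4 libraries were needed, 17811 when every library was limited to an equal number of its highest peaks (a setting chosen after seeing the data), and 17650 to 17968 without replicate 1, 2 or 3.

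The consensus sites lay at transcription start sites far more often than randomly placed sites. Within 1 kb of an annotated start lay 46.5% of the 41228 sites, against 7.26% ± 0.109 (SD, 100 random placements), a ratio of 6.40. Introns held 26.0% of the sites against 39.8%, intergenic sequence 23.7% against 49.6%, and exons 3.81% against 3.29%. Each of these 4 differences had a permutation p of 0.0198 (two-sided), the smallest that 100 placements can give. The share of peaks near a start was 39.9%, 40.4%, 46.3% and 68.6% in replicates 1, 2, 3 and 4.

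The promoters of 18 lists of genes were compared with those of all other protein-coding genes, to ask which cell type's genes were accessible. Of 21915 protein-coding genes, 55.1% had a consensus site within 1 kb of a start. Genes of naive and quiescent T cells had one at 24 of 25 members (96.0%; Fisher's exact p = 8.1e-06, adjusted p = 7.29e-05 over 18 lists). Btg1, an antiproliferative gene, had a relative height of 4.46 ± 0.427 (SD, n = 4). Klf2, a transcription factor of quiescence and T cell trafficking, stood at 3.66 ± 0.379, Txnip, a regulator of glucose uptake, at 3.29 ± 0.410, and Bach2, a repressor of effector genes, at 2.87 ± 0.224. Ccr7, the chemokine receptor for lymph node homing, had a relative height of 1.69 ± 0.279. Il7r, a chain of the interleukin-7 receptor, was called in replicates 1, 2 and 3 and not in replicate 4. Ly6c1 was the 1 member with no promoter peak in any library. In the library labelled replicate 4, 17 of these 25 promoters were called, and 24 in each of the others.

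Housekeeping genes had a consensus promoter site at 21 of 21 members and cell cycle genes at 18 of 18 (Fisher's exact adjusted p = 7.29e-05 and 0.000206). Actb, cytoskeletal actin, stood at 4.47 ± 0.269 (SD, n = 4), and Mcm5, a subunit of the replicative helicase, at 2.98 ± 0.282. Hepatocyte genes had one at 0 of 12 members (Fisher's exact adjusted p = 0.000302), with Alb, which encodes albumin, and Ahsg called in no library. Genes are not independent replicates in these tests. These 4 lists passed the adjusted threshold and the other 14 did not.

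T cell identity genes had a consensus promoter site at 20 of 25 members (80%, Fisher's exact p = 0.0144, adjusted p = 0.0520). Ets1, a transcription factor of lymphocytes, had a relative height of 2.64 ± 0.257 (SD, n = 4), Cd3d, a chain of the T cell receptor complex, 1.62 ± 0.407, Lck, its proximal kinase, 0.996 ± 0.132, and Lat, the adaptor below it, 0.869 ± 0.119. The T cell receptor constant genes Trac, Trbc1 and Trbc2 had no peak within 1 kb of an annotated start in any library. They were the 3 members called in none. The loci of Trac and Trbc1 held 5 consensus sites each, so this speaks only of the annotated starts. Tcf7, a transcription factor of naive T cells, had a promoter peak in replicates 1 and 2 at 0.349 and 0.301, and Lef1 and Bcl11b had one in replicates 1, 2 and 3. The libraries differed at this list, with 22, 22, 20 and 7 members called in replicates 1, 2, 3 and 4, while 10, 10, 13 and 8 of 18 B cell members were called in the same libraries. The direction turned when all 4 libraries were needed and without replicate 1, 2 or 3, each of which needs a call in replicate 4: 8 of 25 members (32%) then had a site, against 45.8% of other genes when all 4 were needed (Fisher's exact adjusted p = 0.315). With the 5' end of each gene only, 15 of 25 members had one (Fisher's exact adjusted p = 0.547). The list passed with 2 libraries needed and with promoter windows of 500 bp and 2.5 kb (Fisher's exact adjusted p = 0.00642, 0.0306 and 0.0275). With replicates 1 and 2 only, a setting chosen after seeing the data, 22 of 25 members had a site (Fisher's exact adjusted p = 0.00354), and 7 lists passed in place of 4; activation and interferon response (adjusted p = 0.0442 and 0.0340) were the others added.

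CD8 lineage genes had a consensus promoter site at 5 of 6 members, activation and exhaustion genes at 17 of 22, interferon response genes at 13 of 16, and cytotoxic effector and memory genes at 16 of 26. Nr4a1, an early response gene of receptor signalling, stood at 3.31 ± 0.439 (SD, n = 4), Id2, a regulator of effector cells, at 1.82 ± 0.131, and Irf9, a subunit of the interferon-activated factor ISGF3, at 2.59 ± 0.581. Prf1, which encodes perforin, was called in all 4 libraries at 1.23 ± 0.299. Gzmb, which encodes granzyme B, and the effector transcription factors Tbx21 and Eomes were called in replicates 1, 2 and 3, with relative heights between 0.171 and 0.513. Ifng, which encodes interferon gamma, was called in replicates 1 and 2, and the chemokine genes Ccl3 and Ccl5 in no library. Adjusted p for these 4 lists lay between 0.0972 and 0.618 (Fisher's exact tests), and activation and exhaustion passed with 2 libraries needed (0.0239). The CD8 lineage list was too short to pass easily. With 2 libraries needed, 6 of 6 members had a site and the adjusted p was 0.0848 (Fisher's exact test). The direction turned for interferon response (6 of 16) and cytotoxic genes (6 of 26) when all 4 libraries were needed and without replicate 1, 2 or 3. The differences from other genes when all 4 were needed were -8.34 and -22.8 percentage points, against 26.2 and 6.46 in the main setting. Cytotoxic genes also lay below other genes with the shorter lists (-5.48 points) and with an equal number of highest peaks (-21.3 points).

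Lists of other cell types had consensus promoter sites at 6 of 20 helper and regulatory T cell genes, 5 of 11 thymocyte genes, 4 of 13 NK cell genes and 9 of 18 B cell genes. The counts were 8 of 20 for myeloid, 6 of 13 for dendritic and antigen presenting, 4 of 16 for erythroid and platelet, 5 of 16 for stromal, endothelial and epithelial, and 6 of 14 for neural genes. Adjusted p for these 9 lists lay between 0.0641 and 0.813 (Fisher's exact tests). Under other settings 4 of them passed, all below other genes in those settings. Against random lists matched on promoter CpG content the direction turned for the NK cell, B cell, myeloid and dendritic lists, from -24.3, -5.09, -15.1 and -8.94 to 5.57, 21.9, 6.66 and 5.36 percentage points. It also turned for the B cell and dendritic lists with 2 libraries needed (9.20 and 4.07 points) and for the B cell list with a 2.5 kb window (8.96 points), and none of these passed. Myeloid genes did with the shorter lists, when all 4 libraries were needed, without replicate 1, 2 or 3, with a 500 bp window and with an equal number of highest peaks (Fisher's exact adjusted p from 0.000988 to 0.0371). Erythroid and platelet genes did when all 4 were needed, without replicate 1, 2 or 3, with the 5' end only and with equal peaks (0.00574 to 0.0350). Stromal, endothelial and epithelial genes did with the shorter lists, without replicate 1, with the 5' end only and with equal peaks (0.00746 to 0.0291), and NK cell genes with the shorter lists (0.0274). Foxp3, the transcription factor of regulatory T cells, had a peak within 1 kb of an annotated start in all 4 libraries at 1.66 ± 0.251 (SD, n = 4). Which of its annotated starts the peak lay at was not determined, so it may not be the main promoter of the gene. Spi1, which encodes PU.1, was called in replicates 1, 2 and 3 at 0.349, 0.276 and 0.388. The naive and quiescent T cell list missed the threshold when all 4 libraries were needed (Fisher's exact adjusted p = 0.0637) and without replicate 1, 2 or 3 (0.0566 to 0.0637). Against random lists matched on promoter CpG content, the cell cycle and hepatocyte lists missed it (permutation adjusted p = 0.0988 for both), while the T cell identity and interferon response lists (0.0012 each), activation and exhaustion (0.0266) and cytotoxic effector and memory (0.0276) passed it.

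**Figure D2:**
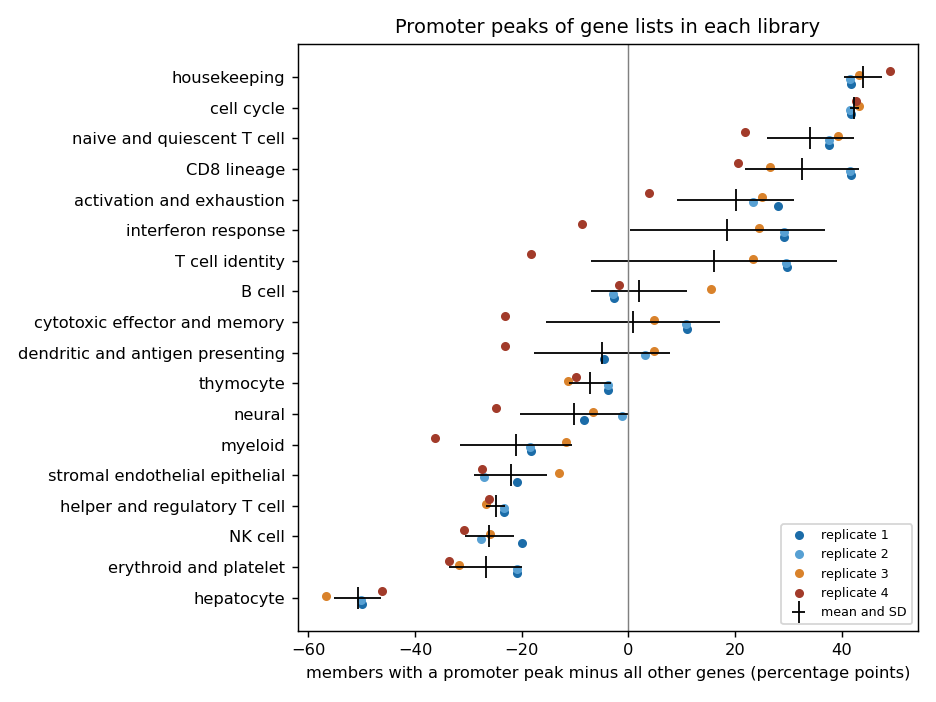
Share of each list's members with a promoter peak minus that of all other genes, in percentage points, with 1 point per library and the mean and SD over the 4 libraries as a bar. The naive and quiescent T cell list lies above 0 in all 4 libraries (mean 34.2), the hepatocyte list below 0 in all 4 (mean -50.7), and the T cell identity list between 23.3 and 29.7 in replicates 1, 2 and 3 and at -18.2 in replicate 4.

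Sites around the same genes, in the gene body plus 25 kb on each side, were counted to include regulatory sites outside promoters. The T cell identity, naive and quiescent T cell, and activation and exhaustion lists each had a median of 7 consensus sites per gene, against 3 in random lists matched on window length. Their permutation p values were 0.0004, 0.0002 and 0.0002 (adjusted p = 0.0024, 0.0018 and 0.0018 over 18 lists), and 0.0002 is the smallest that 10000 random lists can give. Bach2 had 25 sites, Lef1 19, Ccr7 16, Bcl11b 12 and Runx3 11. Of all protein-coding gene models, Gm20388 (216 sites) and Fgfr2 (71) had the most, and both models span several Mb. Foxp1, a regulator of T cell quiescence, followed with 38 sites, then Gm20696 with 32, Gse1 with 31, Vps37b with 29, Wwox with 28, Bach2 and Gm37240 with 25, and Hip1r with 24. The median was 5.5 for CD8 lineage and 5 for B cell genes, 4 for cytotoxic, helper, thymocyte, dendritic, housekeeping and interferon genes, and 3.5 for myeloid and cell cycle genes. It was 2 for stromal and neural genes and 1 for NK cell, erythroid and hepatocyte genes, and none of these 15 lists passed the threshold (permutation adjusted p from 0.319 to 0.665). No list passed when all 4 libraries were needed, with the shorter peak lists, and without replicate 1, 2 or 3. The T cell identity call was lost with a 5 kb window, where housekeeping genes gained one, and the activation and exhaustion call with a 100 kb window and with an equal number of highest peaks. The CD8 lineage list also passed with 2 libraries needed. With replicates 1 and 2 only, chosen after seeing the data, 4 lists passed, the CD8 lineage list among them (permutation adjusted p = 0.0369).

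Peaks at promoters were higher than distal peaks in each library. The median promoter height over the median distal height was 1.85, 1.88, 2.26 and 1.89 in replicates 1, 2, 3 and 4, with a mean of 1.97 ± 0.192 (SD, n = 4). The exact sign-flip permutation test over the 4 libraries gave p = 0.13 (two-sided), the smallest that 4 libraries can give. The highest consensus site by mean relative height, 33.4 ± 14.6, lay on chromosome 17 from 39846781 to 39846920 and overlapped an annotated ribosomal RNA model. The next lay in an exon of Lars2, a mitochondrial leucyl-tRNA synthetase gene, at 20.3 ± 6.74, and within the Zc3h7a gene model, 2339 bp from its nearest annotated start, at 17.8 ± 9.60. The central 36 bases of 6 of the 10 highest sites had more than 1 exact copy in the genome, against 2 of 60 randomly drawn consensus sites.

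The sex chromosomes were compared with the label female. Peaks per Mb on the X chromosome were 0.399 ± 0.0196 (SD, n = 4) of the autosomal density. The promoter of Xist, the RNA gene of X inactivation, had a peak in all 4 libraries at a relative height of 0.447 ± 0.0315. The Y chromosome had 48, 19, 20 and 11 peaks in replicates 1 to 4, and 20, 5, 12 and 6 of these had an exact copy of their central 36 bases outside Y. The 4 Y genes chosen after the peaks were seen, Ddx3y, Eif2s3y, Kdm5d and Uty, had no promoter peak in any library.

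Footprints, short protected stretches within accessible sites, were compared with control windows 100 bp away for matches to 28 motif families. The number of footprints was 170815, 149082, 137861 and 26149 in replicates 1, 2, 3 and 4. CTCF, an architectural protein, had the highest log2 ratio of the share of footprints with a match over that of controls, 6.17 ± 0.49 (SD, n = 4). NRF1 stood at 2.35 ± 0.66, CREB at 2.22 ± 0.62, the ETS family, which includes Ets1 and Gabpa, at 1.77 ± 0.65, and ZNF143 at 1.56 ± 0.29. REST, a repressor of neuronal genes, had 15, 14, 14 and 0 footprints with a match in replicates 1 to 4 and 0 control windows, so its ratio of 3.67 ± 2.45 depends on the pseudocount of 0.5. RUNX stood at 1.38, 1.21, 0.73 and -0.80 in replicates 1 to 4 (mean 0.63 ± 0.99), and PU.1 at 0.51 ± 0.21. TCF7/LEF1 (-0.01 ± 0.54), AP-1 (-0.11 ± 0.31) and EBF1 (0.09 ± 0.15) differed from 0 by less than the spread between libraries. Replicate 4 stood apart in the first 2 of these: TCF7/LEF1 was 0.50, 0.11, 0.13 and -0.77 and AP-1 -0.23, -0.24, -0.32 and 0.36 in replicates 1 to 4. The replicate 4 ratios of RUNX, TCF7/LEF1 and AP-1 rest on few matches among its 26149 footprints. The shares there were 0.0497% against 0.0880% of controls for RUNX, 0.0688% against 0.119% for TCF7/LEF1 and 0.138% against 0.107% for AP-1. The lowest were FOX at -1.20 ± 0.15, GATA at -1.05 ± 0.33 and ROR at -0.98 ± 0.41. A family with the same sign in all 4 libraries has an exact sign-flip permutation p of 0.13, the smallest possible; 12 families lay above 0 in all 4. With footprints not extended, 6 families did, and with shuffled bases as the control, 19 did.

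**Figure D3:**
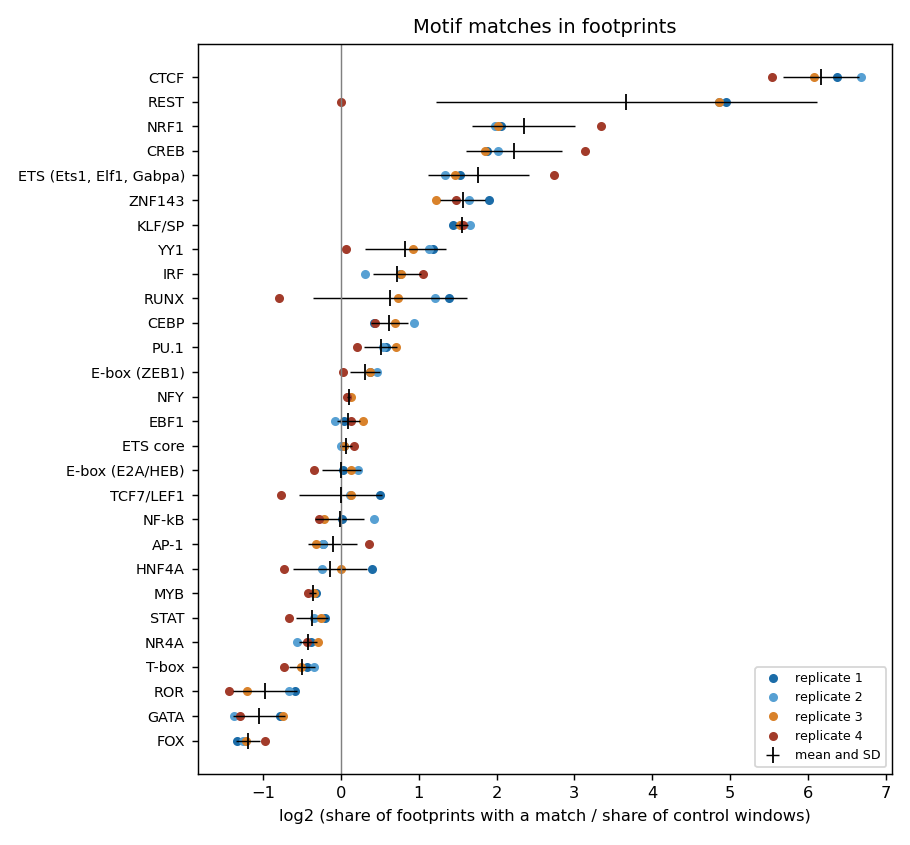
Log2 ratio of the share of footprints with a motif match over the share of control windows, for each of 28 families, with 1 point per library and the mean and SD over the 4 libraries. CTCF lies highest at 6.17 ± 0.49, and RUNX lies above 0 in replicates 1, 2 and 3 and at -0.80 in replicate 4, where it had few matches.

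Motif matches were also compared in the central 100 bp of consensus sites and windows 1 kb away, for 22077 distal and 19151 promoter sites. At distal sites, CTCF matched in 7.66% of sites against 0.0362% of controls (log2 ratio 7.64), PU.1 at a log2 ratio of 3.09, the full ETS motif at 2.77, and RUNX in 3.24% against 1.10% (1.56, Fisher's exact adjusted p = 5.35e-55). AP-1 stood at 0.55, EBF1 at 0.80 and GATA at -0.67 (Fisher's exact adjusted p = 1.62e-08, 0.00888 and 5.51e-06). TCF7/LEF1 matched in 2.36% against 1.76% (0.42, Fisher's exact adjusted p = 2.17e-05). At promoter sites, NRF1 stood at 4.81, CTCF at 4.78, the full ETS motif at 4.38 and CREB at 4.11, while TCF7/LEF1 stood at -1.02, GATA at -1.15 and RUNX at -0.37 (Fisher's exact adjusted p = 1.25e-14, 1.69e-10 and 0.0160). Of 28 families, 16 were more frequent and 2 less frequent than controls at distal sites, and 14 and 9 at promoter sites. REST matched in 13 promoter sites and 0 controls, so its ratio of 4.75 depends on the pseudocount. Sites are not independent replicates. The windows 1 kb away were not matched on base composition, so a ratio above or below 0 may reflect composition and not the family itself. The EBF1 call at distal sites was lost with the shorter lists, when all 4 libraries were needed, without replicate 2 or 3, with site windows of 50 and 200 bp, and with replicates 1 and 2 only (ratios from 0.38 to 1.27, and 0.42 in the last). The REST call at promoters was lost with the shorter lists, when all 4 were needed, and without replicate 1, 2 or 3 (ratios from 1.22 to 2.81), and the full ETS call at distal sites without replicate 2 (2.07). The TCF7/LEF1 ratio at distal sites turned to -0.04, -0.10 and -0.06 without replicates 1, 2 and 3, where all 3 libraries left were needed, and lost its call when all 4 were needed (0.08) and with a 50 bp window (0.23). At promoter sites the RUNX ratio turned to 0.26 with replicates 1 and 2 only and lost its call with 2 libraries needed (-0.18), without replicate 4 (-0.22) and with a 50 bp window (-0.23), and it fell to -1.36, -1.25 and -1.06 without replicates 1, 2 and 3. The AP-1 ratio at promoter sites, -0.36, lost its call with replicates 1 and 2 only (-0.13) and with 2 libraries needed (-0.18).

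Intervals with a cut rate above background covered 27.1, 24.4, 21.3 and 6.88 Mb in replicates 1, 2, 3 and 4 (mean 19.9 ± 9.02, SD, n = 4). They touched 99.9% of the consensus sites in each of replicates 1, 2 and 3 and 46.1% in replicate 4. This contrast was largely fixed by the definition of the consensus, since 40729 of the 41228 sites were called in all of replicates 1, 2 and 3. Consensus sites held 46.2%, 49.6%, 55.6% and 69.3% of the covered length in the same libraries.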

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

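The tests of the Cd8b1 promoter, of single promoters against others of like height, and of the 4 other gene lists, and the search of all loci for a loss like that at Cd8a, were chosen only after the result was seen. So were the allowance for spread in reading the Cd8b1 value and the reading of the crowding value together with the test matched on height and number of sites; taken alone, the crowding value met what was predicted for a cause. Of 62 sets of 4 values, 13 held a library that lay far from the other 3 relative to the range of the set; chance gives about 1 in 20, or 3.1 of 62. The outlying library was replicate 4 in 10 sets, replicate 3 in 2 and replicate 2 in 1.

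Replicate 2 had a median peak width of 180 bp, against 198 to 200 bp in the others. Replicate 3 had a ratio of promoter to distal height of 2.26, against 1.85 to 1.89. Replicate 4 had a promoter peak at 46.2% of genes, against 56.7% to 58.4%, and a cut-rate interval at 46.1% of consensus sites, against 99.9% in each of the others. Of the 41228 consensus sites, 40729 were called in all of replicates 1, 2 and 3, so the contrast at consensus sites was largely fixed by their definition. Promoters of the naive and quiescent T cell list in replicate 4 exceeded other genes by 21.9 percentage points, against 37.7 to 39.4, and those of the interferon response list stood at -8.67 points, against 24.6 to 29.2. Its footprint log2 ratios were 2.73 for ETS (others 1.33 to 1.53), 3.34 for NRF1 (1.98 to 2.06), 3.14 for CREB (1.85 to 2.01), 0.36 for AP-1 (-0.32 to -0.23) and 0 for REST (4.86 to 4.95). The AP-1 ratio in replicate 4 rests on few matches, and REST had 0 there.

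The first pattern is the Cd8a locus, with 8 sites called in both replicates 1 and 2, of which 1 was called in replicate 3 and 0 in replicate 4. Lower depth or enrichment of replicate 3 is argued against, since 92.3% of the 11717 sites with replicate 1 heights in the range of these 8 were called there, and of 3845 genes with at least 8 sites of any height called in replicates 1 and 2, Cd8a was the only one left with at most 1; replicate 4 called 30.5% of sites of that height, so its depth stays open. Peak calls that miss sites cut in replicate 3 stay open: 2 of the 8 sites had a cut-rate interval or footprint there, and 1 of the 7 uncalled ones did, where 42.4% of 894 other uncalled sites of that height did (Fisher's exact p = 0.249). Helper T cells in place of CD8 T cells cannot be told apart from a loss at this locus alone, since the Cd8b1 promoter in replicates 3 and 4 stood at 80.6% and 46.8% of its mean in replicates 1 and 2 (SD of replicates 1 and 2, 17.7% of that mean), at percentiles of 19.4 and 2.15 among 186 other promoters of like height and CpG content, while Zbtb7b stood at 245% and 369%, at percentiles of 98.8 and 97.6 among 85 whose medians were 133% and 181%. A sort for CD8, if one was made, would remove such cells. Cd4 had no promoter peak in any library, which does not separate the libraries. No biological explanation was tested, since the labels give a single group.

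The second pattern is the B cell list, whose promoters in replicate 3 exceeded other genes by 15.5 percentage points, against -2.82 to -1.72 in the others. Lower enrichment that raises weak promoters of all lists alike stays open. The hepatocyte, neural, stromal and erythroid lists together changed by -2 called members in replicate 3 over the mean of replicates 1 and 2. The B cell list gained 3. Calls thus did not rise over these 4 lists as a set, though the stromal list had 7 against 6 and 5. The erythroid list had 4 against 6 and 6, the hepatocyte list 0 against 1 and 1, and the neural list 7 against 7 and 8. Counts of calls do not test heights, and other promoters of like height did rise in replicate 3, to medians of 118% to 175%. B cells in the samples labelled replicates 3 and 4 are a candidate explanation that the test leaves open: at 12 distal B cell sites called in all 4 libraries, replicate 3 stood at a percentile of 99.6 among matched random sites (permutation adjusted p = 0.13) and replicate 4 at 90.3, while at all 38 such sites they stood at 97.4 and 39.3. Distal sites of some other lists also stood high, so a high percentile there was not particular to the B cell list. In replicates 3 and 4 the 11 neural ones stood at 99.5 and 96.3, and the 13 NK cell ones at 99.99 and 49.3. Not all lists did so, with the 15 myeloid ones at 8.25 and 52.7. Pax5, Ebf1, Blk and Bank1 were higher in both replicates 3 and 4 than in replicates 1 and 2. Other promoters of like height called in all 4 had medians of 118% to 175% and 130% to 373% of replicates 1 and 2. Needing a call in replicate 4 may itself raise these medians. Among these promoters Pax5, Ebf1, Blk and Bank1 stood at percentiles of 92.5, 97.6, 100 and 92.1 in replicate 3. In replicate 4 they stood at 99.4, 84.6, 81.8 and 92.1. Cd79a was called in both alone, while Pou2af1 was lower in both. All 13 members called in any library were called in replicate 3, Ms4a1 and Blnk among them, but Ms4a1 and Blnk were not called in replicate 4. Vpreb3, Spib, Fcer2a and Btk were called in none. A sort of naive CD8 T cells, if one was made, would remove B cells, and no biological explanation was tested.

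The third pattern is the T cell identity list, whose promoters in replicate 4 stood at -18.2 percentage points from other genes, against 23.3 to 29.7 in the others. Promoter height and depth are argued against as the whole cause, since 7 of 25 members were called in replicate 4 against a mean of 16.2 (13 to 19 in 95% of lists) in random lists matched on height, a percentile of 0. Crowding of sites did go with fewer calls in replicate 4: at matched height, sites with many neighbours were called less often by -18.9 percentage points (31.1% against 50%). Matched on both height and number of sites, random lists still had a mean of 14.6 members called (11 to 18). The T cell identity list stood at percentile 0.005, so height and crowding together did not account for it. Neither match included promoter CpG content, so its part in these calls stays open. A different cell content of the sample labelled replicate 4 may be a further explanation: heights of this list did not pass at the 49 sites called in all 4 libraries (percentile 40.4, permutation adjusted p = 0.910) or the 28 distal ones (88.1, 0.515), but sites that lost their call are not among these, so it stays open.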

How the results depend on the processing

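The settings replicates 1 and 2 only and an equal number of highest peaks were chosen only after the result was seen. Where no reason is given, the cause was not tested. Peaks per library, pairwise overlap, motif counts at distal and at promoter sites and the cut-rate length kept within their spread or 1.5 times their count under all alternatives run. The share of consensus sites at promoters did not keep within its spread (SD between libraries, 13.5 points). It was 46.5% in the main setting and 67.1% when all 4 libraries were needed. Without replicate 1, 2 or 3 it rose to as much as 67.5%, and with an equal number of highest peaks to 62.3%. Consensus sites numbered 17545 when all 4 libraries were needed, 17650 to 40806 without each replicate in turn, where the low values follow from needing a call in replicate 4, and 17811 with an equal number of highest peaks, where all lists are as short as the shortest. Lists that passed at promoters numbered 7 in place of 4 with the shorter lists and with an equal number of peaks, where those added (NK, myeloid, stromal or erythroid) lay below other genes, and with replicates 1 and 2 only, where those added (T cell identity, activation and interferon) lay above. Lists that passed at loci numbered 0 in place of 3 with the shorter lists and when all 4 libraries were needed, and 0 to 3 without each replicate. The promoter to distal ratio was 2.20 with a 500 bp window and 1.68 to 2.02 without each replicate, and the X density was 0.365 with the shorter lists. Footprint families above 0 in all libraries numbered 6 in place of 12 without extension and 19 with shuffled controls.

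Signs turned for promoters of the T cell identity, interferon and cytotoxic lists when all 4 libraries were needed (-13.8, -8.34 and -22.8 points) and without replicate 1, 2 or 3, and of the cytotoxic list with shorter lists (-5.48) and equal peaks (-21.3). They turned for the NK, B cell, myeloid and dendritic lists with CpG matching (5.57, 21.9, 6.66 and 5.36), for the B cell and dendritic lists with 2 libraries needed (9.20 and 4.07), and for the B cell list with a 2.5 kb window (8.96). Signs turned for footprints of NFY (-0.32 without extension, -0.18 with controls 50 bp away), CEBP (-0.15 without extension, -0.21 shuffled), NR4A (0.035 with controls 50 bp away, 0.50 shuffled), STAT (1.96 shuffled) and MYB (0.091 shuffled). At distal sites they turned for NR4A (0.048 when all 4 libraries were needed), MYB (-0.18, 50 bp window) and FOX (0.23, 200 bp window). Without each replicate the ratios there ranged from -0.10 to 0.45 for TCF7/LEF1, -0.64 to 0.15 for NR4A and 0 to 2.81 for REST. In the same settings they ranged from -0.18 to 0.067 for MYB and from -0.31 to 0.10 for FOX, neither of which had a call in the main setting. At promoter sites the signs turned for the ZEB1 E-box (0.10, 2 libraries needed) and RUNX (0.26, replicates 1 and 2 only), and the ratio for IRF ranged from -0.68 to 0.25 without each replicate. Of the other alternatives, 35 of 234 for list promoters moved a list across the threshold without a change of sign, 29 of them into a call, and 21 of 216 for list loci did, 18 of them out of a call. Replicate 4, with the fewest tags, called 43.1% of the sites called in replicates 1, 2 and 3; no setting matched depth between libraries.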

Other observations

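The tests of single libraries at the sites of gene lists, the height-matched comparison of lists other than T cell identity in replicate 4, and the ranking of loci by loss in replicate 3 were chosen only after the result was seen.

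Sites at the loci of NK cell genes stood apart between libraries, at the 17 called in all 4 libraries. These loci differed in their number of consensus sites, with 10 at Fcgr3, 5 at Nfil3 and 0 at Klra4 and at Klra7. The median log2 deviation from the mean of the 4 libraries was -0.33 in replicate 2 and 0.24 in replicate 3 (permutation p = 0.0002 each, the smallest possible, adjusted p = 0.0072 over 72 comparisons). At the 13 distal ones it was -0.28 and 0.24 (permutation adjusted p = 0.0112). The Fcgr3 promoter, a low-affinity antibody receptor gene, had relative heights of 0.600, 0.375, 1.04 and 1.21 in replicates 1 to 4. At 12 distal B cell sites, replicate 1 deviated by -0.19 (permutation adjusted p = 0.0224 over 56 comparisons). No other list passed the threshold in any library, T cell lists included. In these tests, and in those of B cell and T cell identity sites above, random sites were drawn singly across the genome. The sites of a list lie together at its loci, so the p-values take neighbouring sites as independent and may be too small.

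In replicate 4, 8 of 18 B cell promoters were called, against a mean of 4.96 (3 to 7 in 95% of lists) in random lists matched on height in replicates 1, 2 and 3. Interferon response promoters numbered 6 against 9.35 (7 to 12), cytotoxic ones 6 against 8.57 (6 to 12), and naive and quiescent ones 17 against 19.8 (17 to 23). These random lists were not matched on promoter CpG content.

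Genes with at least 8 sites called in both replicates 1 and 2 kept a median of 80% of them in replicate 3. After Cd8a, with 1 of 8, the lowest were Pi16, Poli and Wbp4 with 2 of 8 each, and Lims1 and Plcg1, a phospholipase of receptor signalling, with 3 of 11 each.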
